A study of Cricetulus griseus and Homo sapiens with 4 samples.

How the data were processed

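The values are log2 ratios of a 2-colour array as the authors deposited them in the series' value table, 1 column per array and 1 line per array feature. The direction, Cy5 (Pcdh7) over Cy3 (empty vector), is that of the titles and dyes per the labels. Per the labels' protocols, cells grown in flasks were transfected by lipid reagent, total RNA was taken after 48 h, and labelled cRNA was made by linear amplification. Image analysis, background correction and dye normalization are not given in the sources used here. The base of the logarithm was settled from the values: the lowest value on every array is -6.64, the log2 of 0.01, and 2 to the power of a value is a whole multiple of 0.001 for 99.6% to 99.8% of the values on an array, within the rounding of the deposited decimals. Ratios were therefore rounded, and floored at 0.01, before deposit. Each array's median is at 0.00, so the ratios were centred before deposit by a step not stated. The scale is thus settled from the values, while the direction rests on the labels alone and the method of centring is unknown. A value at the floor (52, 104, 94 and 77 features on A23 replicates 1 and 2 and HEK replicates 1 and 2) is an upper bound of the ratio before flooring. Signal over background is unknown, so how far a floor value reflects a fall of the RNA is not known. A fitted mean that holds one may understate or overstate the fall.

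The arrays held 35014, 36234, 36972 and 36784 values, in the same order, of 41174 features; the rest were empty, and the 29563 features with a value on all 4 arrays (71.8%) were tested. No scanner intensities were used here, so background correction, within-array loess and a filter on dim probes could not be varied, and signal over background is unknown. No array had its dyes swapped, so a gene-specific dye effect has the same sign as an effect of Pcdh7 on every array. Gene names came from the platform's annotation: 31700 features had 1 symbol, 47 several and 9427 none, and features with several were named by none. Symbols of the gene lists were brought to the annotation's current ones in 24 cases. The probes were designed on mouse transcripts and were read with hamster and human RNA. No genome coordinates were used.

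Groups came from the titles. On A23 replicate 1 the title and the design text name A23 in both channels, while the source label of its Cy3 channel names HEK; it was kept as A23, and its values without that array are given. The labels call the arrays of a line biological replicates, so the p-values rest on the spread between 2 transfections within each line, pooled over both lines. Where both arrays of a line are at the floor, that line shows no spread. The p then rests on the other line and limma's prior, as for Kif11 and Gm39091 in A23 and Gm26698 in HEK. Whether cultures were otherwise separate is not stated.

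Each probe was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 1 coefficient per cell line over all 4 arrays, so that both lines share 1 estimate of the spread (2 residual and 4.98 prior degrees of freedom). Each line's mean log2 ratio, the difference HEK minus A23 and the mean of both lines were tested against 0, two-sided, with Benjamini-Hochberg adjustment over all 29563 probes at 0.05. The SE of a gene is that of the moderated fit. The empty vector enters as the Cy3 channel of each array and not as separate samples, so its own spread is part of that of the ratio. Standard deviations with n = 2 are over the 2 arrays of a line.

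Before the data were examined, 26 gene lists were fixed: delta-protocadherins, clustered protocadherins, classical cadherins and catenins, desmosome and tight junction, integrins and focal adhesion, phosphatase 2A and SET (reported PCDH7 partners, with SET-binding proteins, catalytic subunits of phosphatase 1 and, in error, Taf1), ERK-induced genes, SRF and YAP targets, Wnt targets, TGF-beta targets, NF-kB and inflammatory genes, interferon-stimulated genes, unfolded protein response, heat shock, p53 targets, cell cycle, histones, cytosolic ribosomal proteins, oxidative phosphorylation, glycolysis and hypoxia, cholesterol and fatty acid synthesis, extracellular matrix, apoptosis regulators, fibroblast markers, HEK-type markers and housekeeping genes. They were tested with camera on the mean over a gene's probes, with a preset inter-gene correlation of 0.01 and adjustment over the lists; camera with an estimated correlation and fry were alternatives. A member counts as higher or lower if any of its probes passed, and a member with probes called each way is counted as neither.

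The rule for named genes, also fixed before the data were examined, was for each line the 12 genes with the largest positive and the 12 with the largest negative mean among probes that passed and had the same sign on both arrays, 1 probe per gene, filled to 10 by the smallest unadjusted p where fewer passed, and 6 each way for the difference and for the mean of the lines. Of each list, up to 4 members that passed, or else the 2 with the smallest p, were named. Pcdh7 was always named. Uncharacterised symbols were counted and not named under this rule. Gm39091 and Gm26698 are named outside it, singled out after their values were seen.

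Neighbouring feature numbers had similar ratios, and the correlation peaked again at a distance of 215 features on every array, between 0.107 and 0.208, so features were laid out in 206 rows of 215 to infer their position. As an alternative chosen after seeing the data, the median of the surrounding 15 by 15 features was taken off each value. The phosphatase list without Taf1 was also chosen after seeing the data. A further 18 gene families, defined by the start of the symbol, were also tested after the data were seen. Other alternatives fixed beforehand were centring each array on the median of the tested probes, scaling the arrays to the same spread, robust moderation, leaving out values of 0 or at the floor, leaving out probes with small ratios, gene means, a replicate block, a threshold of 0.1, an added threshold of 1 on the log2 scale, each line fitted alone, a fold rule without a test, and leaving out each array. Tested on simulated arrays with the fitted spread and 200 changed probes among 29563, the fit recovered 52% of changes of 2 on the log2 scale in A23 and 53% in HEK, and 0% and 1% of changes of 1, with 2 and 1 false calls. These rates hold for that setting alone. The adjustment is looser where more probes change, and 3076 passed in the HEK data, so they do not describe HEK.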

Results

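Gene expression was measured on 4 whole-genome mouse oligonucleotide arrays, each hybridised with 2 colours. On every array the Cy5 channel held RNA from cells transfected with Pcdh7, a protocadherin of the cadherin superfamily of adhesion molecules, in a cytomegalovirus promoter vector, and the Cy3 channel held RNA from cells given the empty vector. Cells were harvested after 48 h. The cells of 2 arrays were A23, a Chinese hamster fibroblast line that served as the recipient of a radiation hybrid panel, and those of the other 2 were HEK, a human embryonic kidney line, with 2 biological replicates per line. The series belongs to a study that mapped regulatory loci for gene expression with radiation hybrids, and transfecting a gene asks which transcripts change when it is overexpressed. Of 41174 features, 29563 had a log2 ratio on all 4 arrays, and 23724 of these carried 1 mouse gene symbol, for 16282 genes. Hamster and human RNA was read by mouse probes, so a probe's value depends also on how well it matches the other species. With 4 arrays, their number limits the precision of every value.

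Pcdh7 itself, read by 2 probes, was not higher in the transfected cells of either line. Its mean log2 ratio over both probes was -0.20 ± 0.28 (SD, n = 2 arrays) in A23, with -0.40 on replicate 1 and -0.01 on replicate 2. In HEK it was 0.05 ± 0.19 (SD, n = 2 arrays), with -0.08 and 0.19. The 95% confidence interval from limma ran from -0.69 to 0.28 in A23 and from -0.43 to 0.54 in HEK, so that a rise above 1.21-fold in A23 or 1.45-fold in HEK at these probes lay outside it. The adjusted p was 0.596 in A23 and 0.866 in HEK over 16282 gene means. The highest single value was 0.50, at 1 of the probes on HEK replicate 2. Whether these probes lie within the transfected insert is not known here, so they do not check the transfection.

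**Figure D1:**
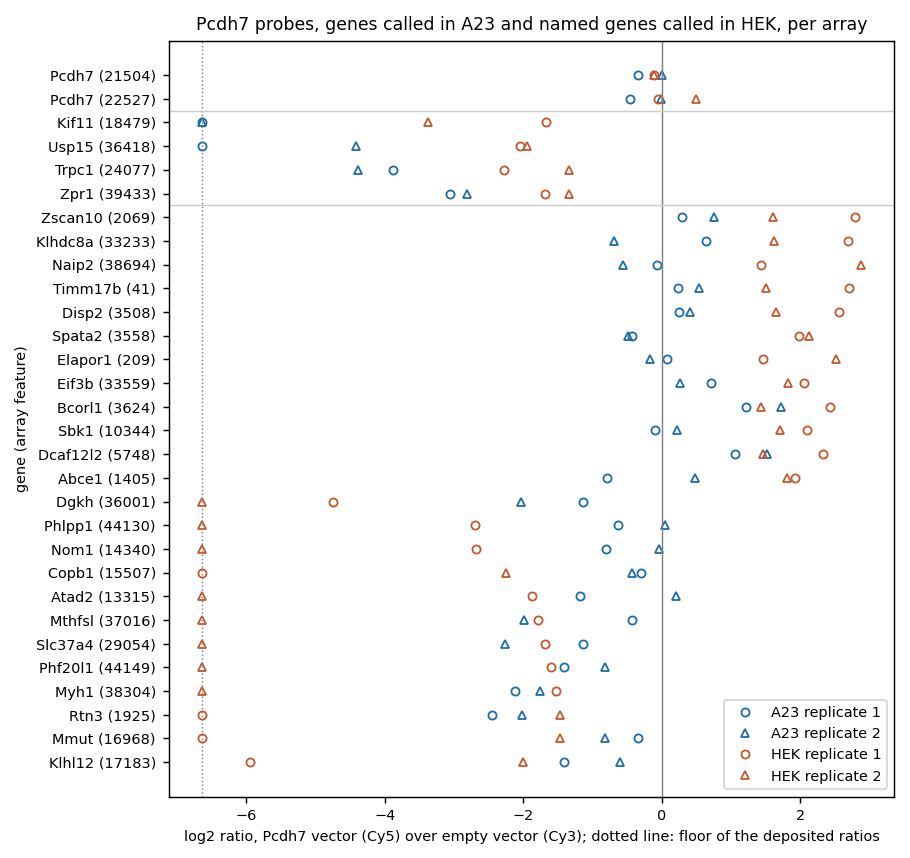
Log2 ratio of Pcdh7-transfected over empty-vector cells (horizontal axis) on each of the 4 arrays for the 2 Pcdh7 probes, the 4 named genes called in A23 and the 24 named genes called in HEK (vertical axis, with the array feature number). Circles are replicate 1 and triangles replicate 2 of A23 (blue) and HEK (orange), and the dotted line is the floor of the deposited ratios; the Pcdh7 points lie between -0.46 and 0.50, and 11 of the 12 named genes that fell in HEK have 1 HEK array at the floor.

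In A23 cells transfected with Pcdh7, probes of 4 named genes fell and none rose. The probe for Kif11, a kinesin motor of the mitotic spindle, was at the floor on both arrays, a ratio at or below 0.01 (adjusted p = 0.0080). With no spread in A23, its p rests on the spread in HEK and on limma's prior. The probe for Usp15, a deubiquitinating enzyme, was at the floor on replicate 1 and at -4.41 on replicate 2 (adjusted p = 0.0399). The probe for Trpc1, a cation channel of the plasma membrane, fell by 4.13 on the log2 scale (SE 0.29, n = 2, adjusted p = 0.0198). The probe for Zpr1, a zinc finger protein, fell by 2.94 (SE 0.22, n = 2, adjusted p = 0.0254).

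Over all 29563 probes, limma called 6 in A23, all lower, and 5592 had an unadjusted p under 0.05. The remaining 2 calls, singled out after their values were seen, were Gm39091, an uncharacterised transcript at or below a ratio of 0.01 on both arrays (adjusted p = 0.0011), and feature 28780, which has no symbol in the annotation and fell by 2.68 (adjusted p = 0.0399). Of the called genes, Trpc1 and Zpr1 each had 1 other probe, with a mean log2 ratio of 0.48 and 0.06, the other probe of Kif11 was at -0.32, and the 4 other probes of Usp15 lay between -0.09 and 0.17. Among genes just outside the threshold, Lypd6 had a mean log2 ratio of 2.14 (SE 0.23), Elapor2 of 2.12 (SE 0.21), the linker histone gene H1f6 of 2.07 (SE 0.23), Fam174c of 1.88, Ncoa4, a receptor for the breakdown of ferritin, of 1.81, the matrix proteoglycan gene Bgn of 1.81, the cell cycle repressor E2f7 of 1.74. Ankrd29 and the arginine methyltransferase gene Carm1 had 1.64 each and the MHC class I gene H2-T22 had 1.58. These genes had adjusted p between 0.0549 and 0.0612. On the lower side, Srp54b had -2.88 (SE 0.32), Med12l -2.54, Eml6 -2.41, Mctp2 -2.21, Ctso, a lysosomal protease gene, -2.15 and Zfp708 -1.95, with adjusted p between 0.0511 and 0.0612. The only other probes of Lypd6, Ankrd29 and Eml6 had the opposite sign, at -1.26, -0.53 and 0.65. The count was 572 at an adjusted p under 0.1, and with arrays scaled to the same spread it was 1960, of which 621 were higher and 1339 lower. It was 818 without A23 replicate 1, 506 without A23 replicate 2 and 2 on leaving out either HEK array alone, when Usp15, Trpc1 and Zpr1 no longer passed and Kif11 did. Usp15 was also lost when each array was centred.

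Of 26 gene lists, 1 stood apart in A23, the cytosolic ribosomal proteins, which were higher. Of 28 measured ribosomal genes 27 had a positive mean, the median log2 ratio was 0.41 (SD over genes 0.29) against 0.06 for all genes, and it was 0.56 on replicate 1 and 0.24 on replicate 2. The examples with the smallest p were Rps12, at 1.22 (SE 0.22, adjusted p = 0.0836), and Rps18, at 1.12 (SE 0.31, adjusted p = 0.158). In camera the list had an adjusted p of 0.0034, and adjusted p = 0.838 with an estimated correlation. No ribosomal gene passed over all probes, and 1 was higher adjusted over the list alone. As a measured fact beside it, the 900 measured genes of olfactory, vomeronasal and taste receptors, a family chosen after the data were seen, had a median of 0.27 (SD over genes 0.45) in A23. Without A23 replicate 1 the ribosomal list had an adjusted p of 0.198.

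The other lists did not pass in A23, and over all of them Kif11, of the cell cycle list, was the only member past the threshold over all probes, while 102 of the 404 measured list members had an unadjusted p under 0.05 in limma. The classical cadherins and catenins, which join cells through the cytoskeleton, came closest, with a median of -0.23 (SD over genes 0.41), 1 of 11 genes positive and an adjusted p of 0.0763. The median was -0.14 with the local median taken off (adjusted p = 0.149) and -0.38 with arrays scaled (adjusted p = 0.0314). In camera with an estimated correlation the adjusted p was 0.838. Among the members of this list plakoglobin (Jup) was at -0.94 (SE 0.22) and a probe of alpha-catenin (Ctnna1) at -0.78 (SE 0.24). The only other probe of Ctnna1 was at 0.45, and the probe given was at -0.45 with the local median taken off. The phosphatase and SET list, of reported partners of PCDH7 and, in error, Taf1, had a median of 0.30 (SD over genes 0.37; adjusted p = 0.127), the interferon-stimulated genes -0.12 (adjusted p = 0.22), the unfolded protein response 0.20 (adjusted p = 0.361) and oxidative phosphorylation 0.22 (adjusted p = 0.376). Adjusted over the list alone, 13 lists had calls in A23 and 13 had none. Among the former, the integrin and focal adhesion list had 2 genes higher (Itga3 1.32, SE 0.27, and Itgb3 1.34, SE 0.28, whose only other probe was at -0.26), the cell cycle list 2 lower, the fibroblast markers 1 higher and 2 lower, and the extracellular matrix and TGF-beta target lists 1 each way. The ribosomal and glycolysis lists had 1 higher, and the Wnt, NF-kB, interferon, histone, cholesterol and apoptosis lists 1 lower. The test direction opposed the sign of the median in 3 lists, the clustered protocadherins, fibroblast markers and housekeeping genes, and that of the mean in the delta-protocadherin and cell cycle lists. Centring each array turned the medians of the integrin list (0.04 to -0.03), the fibroblast markers (0.06 to -0.01) and the housekeeping genes (0.04 to -0.03).

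In HEK cells transfected with Pcdh7, 12 named genes that rose did so by 3.64-fold to 4.57-fold. They included Zscan10, a zinc finger factor of pluripotent cells (log2 ratio 2.19, SE 0.32), Klhdc8a (2.15, SE 0.38), Naip2, a sensor of the inflammasome (2.15, SE 0.36), Timm17b, of the mitochondrial import machinery (2.11, SE 0.31), and Disp2 (2.10, SE 0.27). Spata2, an adaptor of the deubiquitinase CYLD, rose by 2.05 (SE 0.21), Elapor1 by 1.99 (SE 0.29) and the translation initiation factor gene Eif3b by 1.93 (SE 0.23). The corepressor gene Bcorl1 rose by 1.92 (SE 0.30), the kinase gene Sbk1 by 1.90 (SE 0.23), Dcaf12l2 by 1.89 (SE 0.28) and Abce1, a factor of ribosome recycling, by 1.86 (SE 0.32). All 12 had an adjusted p of 0.0446 and, as the naming rule required, a positive value on both HEK arrays.

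The 12 named genes that fell in HEK had means between -5.70 and -3.98, and 11 of them were at the floor on 1 HEK array. The size of those 11 means rests largely on that array. Ranked by size, the 12 are not typical of the calls. Of the 3076 probes called in HEK, 21 held a floor value on any array, and the median size of the called means was 1.12. Dgkh, a diacylglycerol kinase gene, was at -4.75 on replicate 1 and at the floor on replicate 2 (adjusted p = 0.0286). Phlpp1, a phosphatase of the kinase Akt, was at -2.70 and the floor, Nom1 at -2.68 and the floor, and Copb1, of the COPI coat, at the floor and -2.25 (adjusted p = 0.0446 for each). Klhl12 was at -5.94 and -2.01 (adjusted p = 0.0446). The value of the array not at the floor was -1.88 for Atad2, -1.79 for Mthfsl, -1.68 for the glucose-6-phosphate transporter gene Slc37a4, -1.60 for Phf20l1, -1.52 for the myosin gene Myh1, -1.47 for the reticulon gene Rtn3 and -1.47 for the methylmalonyl-CoA mutase gene Mmut, with adjusted p between 0.0453 and 0.0498. Of the 24 named genes, 8 of those that rose and 8 of those that fell had other probes, and for 2 and 4 genes at least 1 of these had the opposite sign. The only other probe was at -0.10 for Spata2, -0.54 for Abce1, 0.23 for Phf20l1 and 0.14 for Myh1. Other probes of Atad2 ran from -1.57 to 1.17 and those of Rtn3 from -0.33 to 0.81. The only other probes of Dgkh, Nom1, Copb1 and Klhl12 had the same sign, at -0.05, -1.33, -0.08 and -0.47.

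Over all probes limma called 3076 in HEK, 1665 higher and 1411 lower, for 2274 genes, and 11270 had an unadjusted p under 0.05. The calls lay close to the threshold, with 5 at an adjusted p under 0.04 and 4881 under 0.06. Centring each array, which takes 0.23 off HEK replicate 1 and 0.13 off replicate 2, left 367 higher and 1618 lower. The count was 0 with arrays scaled to the same spread, 49 without HEK replicate 1 and 72 without HEK replicate 2. On HEK replicate 1 the log2 ratios followed position: features numbered up to 4445 had a median of 0.83 there, against -0.06 on replicate 2. That part of the slide held 21.3% of the higher calls, 4.32% of the lower calls and 9.65% of all tested probes, and 7 of the 12 named genes that rose, of which Elapor1 had 1.24 in place of 1.99 with the local median taken off.

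**Figure D2:**
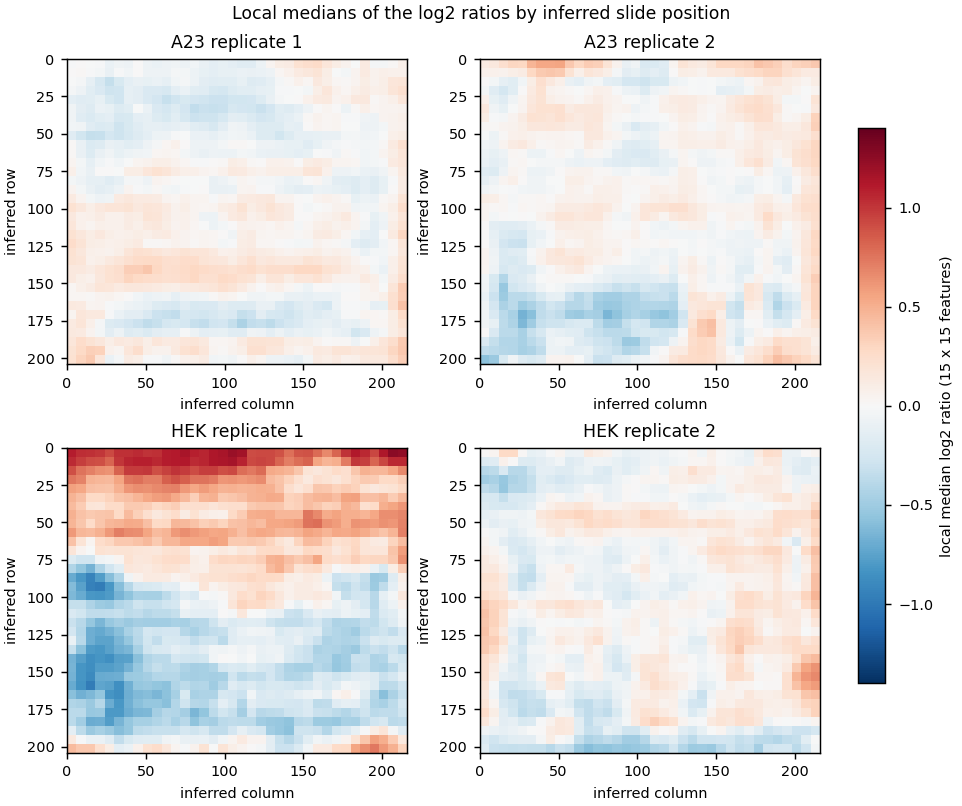
Median log2 ratio of Pcdh7 over empty vector in windows of 15 by 15 features (colour), by row and column inferred from the feature number, for the 4 arrays. On HEK replicate 1 the local median runs from -1.03 to 1.37 with high values in the first rows, while its SD over features is 0.46, against 0.14 to 0.19 on the other arrays.

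Cytosolic ribosomal proteins were also higher in HEK. Of 28 genes 4 rose, Rpl30 by 1.24 (SE 0.23), Rpl11 by 1.24 (SE 0.29), Rps2 by 1.13 (SE 0.28) and Rps19 by 1.01 (SE 0.22), none fell and 26 had a positive mean. The list's median was 0.60 (SD over genes 0.37) against 0.16 for all genes, with 0.97 on replicate 1 and 0.22 on replicate 2, and its adjusted p in camera was 0.0202, or adjusted p = 0.952 with an estimated correlation. Adjusted over the list alone, 5 genes were higher. The classical cadherins and catenins were lower, with a median of -0.44 (SD over genes 0.43), 2 of 11 genes positive and an adjusted p of 0.0485, or adjusted p = 0.952 with an estimated correlation. Among them Jup fell by 0.95 (SE 0.22), the only member past the threshold over all probes, and adjusted over the list alone none passed, with 6 at an unadjusted p under 0.05 in limma. After the local median was taken off, a setting chosen after seeing the data, the adjusted p was 0.114 for the ribosomal list and 0.123 for the cadherin list; without HEK replicate 1 it was 0.611 and 0.19. With the correction the median was 0.49 for the ribosomal list and -0.14 for the cadherin list. The cadherin list also did not pass in camera with arrays centred or with probes as members. The receptor family named above had a median of 0.46 (SD over genes 0.58) in HEK, and 14.7% of its 937 probes were called, against 9.90% of the other named probes.

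**Figure D3:**
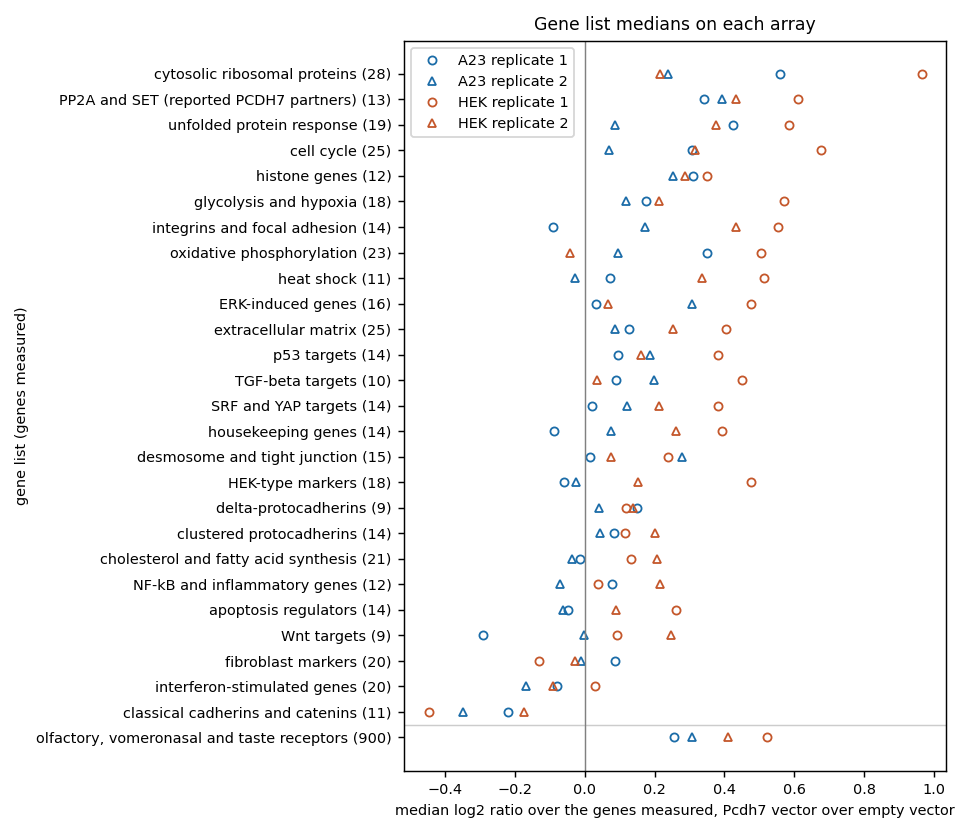
Median log2 ratio of Pcdh7 over empty vector (horizontal axis) over the measured genes of each gene list (vertical axis, with their number) on A23 (blue) and HEK (orange) arrays, replicate 1 as circles and replicate 2 as triangles. The ribosomal list has a positive median on all 4 arrays, from 0.22 to 0.97, and so has the family of 900 receptor genes in the last line, from 0.26 to 0.52.

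Over all 26 lists, 58 of the 404 measured members passed over all probes in HEK, against 2274 of all 16282 genes. List members thus passed at about the rate of genes in general, which holds for the members named here and below. An unadjusted p under 0.05 in limma was reached by 203 of the 404 members in HEK, and by 38.1% of all probes. A member counts if any of its probes reached it, so the 2 shares are not alike. The share over all genes is not given here. Among the adhesion lists in HEK, the protocadherin Pcdh1 rose by 1.17 (SE 0.22), the only one of 9 delta-protocadherins to pass, and it alone was higher adjusted over the list alone. Of 14 clustered protocadherins 2 rose, Pcdhga7 by 1.05 (SE 0.21) and Pcdha9 by 0.95 (SE 0.21), and 2 fell, Pcdhb9 by 1.62 (SE 0.24) and Pcdha4 by 1.17 (SE 0.23), with 6 higher and 3 lower adjusted over the list alone. Of 14 integrin and focal adhesion genes 4 rose over all probes and adjusted over the list alone: Itgb3 by 1.84 (SE 0.28), Itga1 by 1.19 (SE 0.21), Vasp by 1.10 (SE 0.24) and Actn1 by 0.95 (SE 0.22). Of 15 desmosome and tight junction genes Cldn7 rose by 1.03 and Dsp by 0.93, and Dsc2 fell by 2.06 (SE 0.44), with 3 higher and 1 lower adjusted over the list alone. Of 25 extracellular matrix genes Timp3, Thbs2 and Bgn rose, by 1.06, 1.07 and 0.95, and none passed adjusted over the list alone, where 14 had an unadjusted p under 0.05 in limma. None of these lists passed in camera, with adjusted p of 0.894 for either protocadherin list, 0.249 for integrins, 0.865 for junctions and 0.277 for the matrix.

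Among stress and metabolic lists in HEK, 3 of 19 genes of the unfolded protein response rose, Xbp1 by 1.22 (SE 0.21), Ddit3 by 0.95 (SE 0.21) and Edem1 by 1.00 (SE 0.25), with 6 higher adjusted over the list alone. Of 18 glycolysis and hypoxia genes 4 rose, among them Aldoa by 1.43 (SE 0.28), Adm by 1.38 (SE 0.26) and Pkm by 1.03 (SE 0.22), and Hk1 fell by 1.13 (SE 0.21). Of the 5 other Hk1 probes 4 had the opposite sign. Adjusted over the list alone 6 genes were higher. No heat shock gene passed over all probes (6 of 11 at an unadjusted p under 0.05 in limma), but 5 were higher adjusted over the list alone, with Hspa1a at 0.97 (SE 0.25). Of 23 genes of oxidative phosphorylation none passed either way, and 5 had an unadjusted p under 0.05. Of 21 cholesterol and fatty acid genes Acaca and Scd1 rose, by 1.07 and 0.95, and Insig1 and Nsdhl fell, by 1.57 and 1.21, with 3 higher and 2 lower adjusted over the list alone. In camera these lists had adjusted p of 0.0909 (unfolded protein response), 0.14 (glycolysis), 0.237 (heat shock), 0.865 (oxidative phosphorylation) and 0.992 (cholesterol).

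Among signalling lists in HEK, the ERK-induced gene Spry1 rose by 0.89, 1 of 16 measured, and a probe of Ereg by 0.98, while the other Ereg probe was at -3.53 (3 genes higher adjusted over the list alone). Of 14 SRF and YAP targets Cnn1 rose by 1.18 (SE 0.23) and Edn1, the endothelin gene, fell by 2.29 (SE 0.35). The Wnt target Apcdd1 fell by 1.12, 1 of 9, and the TGF-beta target Bambi by 1.49 (SE 0.25), 1 of 10; the counts of these 3 lists were the same adjusted over the list alone. Of 12 NF-kB and inflammatory genes Vcam1 fell by 2.28 (SE 0.25) and Nfkb2 rose by 0.85, with 1 higher and 2 lower adjusted over the list alone. Of 20 interferon-stimulated genes Oas2 fell by 1.32 (SE 0.29), and Rsad2 had probes called each way, with 1 higher and 2 lower adjusted over the list alone. The phosphatase and SET list of 13 genes had an adjusted p of 0.277 in camera and of 0.0212, higher, in fry, which asks only whether its genes move one way. Adjusted over the list alone 4 were higher and 1 lower. Its only member past the threshold over all probes was Taf1, a TFIID subunit that is neither a phosphatase nor SET and was listed in error, which fell by 1.21 (SE 0.23). Without Taf1, a setting chosen after seeing the data, none of 12 passed over all probes or adjusted over the list alone, with 8 having an unadjusted p under 0.05 in limma. Its median was then 0.48 (SD over genes 0.45) and the adjusted p was 0.119 in camera and 0.0374 in fry. In camera the other adjusted p were 0.865 (ERK), 0.783 (SRF and YAP), 0.992 (Wnt), 0.865 (TGF-beta), 0.992 (NF-kB) and 0.374 (interferon).

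Among the remaining lists in HEK, the mitotic genes Birc5, Aurka and Cdc20 rose, by 1.06, 0.98 and 0.95, of 25 cell cycle genes, and Kif11 fell by 2.52 (SE 0.38), with 9 higher and 2 lower adjusted over the list alone. Of 14 p53 targets Bbc3 rose by 1.32 (SE 0.24), Sesn2 by 1.14 (SE 0.23) and Btg2 by 0.84, and Trp53inp1 fell by 1.81 (SE 0.29), with 3 higher and 1 lower adjusted over the list alone. Of 14 apoptosis regulators Diablo fell by 1.23 (SE 0.24), with 3 higher and 1 lower adjusted over the list alone. No histone gene of 12 passed over all probes (6 at an unadjusted p under 0.05 in limma), and 3 were higher and 2 lower adjusted over the list alone. Of 18 HEK-type markers Gal, Igfbp5 and Nefm rose, by 1.29, 1.17 and 0.96, and Lin28b fell by 1.58; of 20 fibroblast markers S100a4 rose by 1.26 and Pdgfra fell by 0.89. Adjusted over the list alone, 4 HEK-type markers were higher and 1 lower, and no fibroblast marker passed, with 11 at an unadjusted p under 0.05 in limma. Of 14 housekeeping genes none passed over all probes or adjusted over the list alone, with 9 at an unadjusted p under 0.05 and a median of 0.52 (SD over genes 0.36). In camera the adjusted p were 0.249 (cell cycle), 0.754 (p53), 0.865 (apoptosis), 0.754 (histones), 0.783 (HEK-type), 0.666 (fibroblast) and 0.249 (housekeeping). Of the 57 list members named as past the threshold in HEK, 10 lost over 1.5 times in size when the local median was taken off: Scd1 (0.95 to 0.36), Gal (1.29 to 0.69), Aurka (0.98 to 0.55), Cldn7 (1.03 to 0.59), Rps19 (1.01 to 0.59), Bambi (-1.49 to -0.90), Rpl30 (1.24 to 0.76), Thbs2 (1.07 to 0.67), Bbc3 (1.32 to 0.84) and Nfkb2 (0.85 to 0.55). Of the 30 with other probes, 16 had at least 1 of opposite sign: Ereg, Rsad2, Hk1, Edem1, Lin28b, Igfbp5, Acaca, S100a4, Insig1, Nsdhl, Pkm, Rpl11, Dsp, Vasp, Pcdha9 and Pdgfra. The test direction opposed the sign of the median in 6 HEK lists, the clustered protocadherins, the Wnt, TGF-beta and NF-kB lists, the apoptosis regulators and the interferon list. Centring each array turned the HEK medians of the delta-protocadherins (0.13 to -0.05) and of the interferon list (0.00 to -0.18), and brought those of the TGF-beta targets and apoptosis regulators from 0.18 and 0.17 to just below 0.

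No gene with a characterised name differed between the lines past the threshold. Spata2 had the smallest p on the higher side, at 2.05 in HEK and -0.46 in A23 (SE of the difference 0.30, adjusted p = 0.321), followed by Fkbp1b (difference 2.35), Kif11 (at least 4.12, since A23 was at the floor), Cfap70 (2.10), the cell cycle factor gene E2f4 (2.08) and the threonyl-tRNA synthetase gene Tars (1.96). On the lower side were Pdcd6ip, of membrane remodelling (difference -2.69, SE 0.31, adjusted p = 0.305), Taf1a (-2.73), Angel2 (-2.61), Elapor2 (-2.02), Emc8 (-1.88) and Dgkh (-4.12, with 1 HEK array at the floor). Of the 6 genes named each way, 5 and 6 had other probes, and for 3 and 3 at least 1 had a difference of opposite sign. These were Fkbp1b, Kif11 and Cfap70 on the higher side and Pdcd6ip, Taf1a and Elapor2 on the lower. The contrast of HEK minus A23 called 2 probes, singled out after their values were seen: Gm39091, at the floor on both A23 arrays and at -1.02 ± 0.58 (SD, n = 2) in HEK, and Gm26698, at the floor on both HEK arrays and at -1.18 ± 0.36 (SD, n = 2) in A23 (adjusted p = 0.0184 for each). None of the 26 lists differed in camera, with 1, the housekeeping genes, at an unadjusted p under 0.05 (adjusted p = 0.324). Of the 404 list members 0 passed over all probes, with 58 at an unadjusted p under 0.05 in limma, and adjusted over the list alone 2 interferon-stimulated genes, 1 cell cycle gene and 1 HEK-type marker were higher in HEK and Taf1, of the phosphatase list, lower. The unadjusted p was under 0.05 for 2409 probes, and the count of calls was 190 without A23 replicate 1, 220 without A23 replicate 2, 9 without HEK replicate 1 and 17 without HEK replicate 2.

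Over both lines, the genes that rose most were Bcorl1 (mean log2 ratio 1.70, SE 0.21), Dcaf12l2 (1.59, SE 0.20), the integrin gene Itgb3 (1.59, SE 0.20), Lypd6 (1.57, SE 0.16), the mitochondrial carrier gene Sfxn1 (1.45, SE 0.18) and Pigt, of GPI anchor attachment (1.44, SE 0.15), with an adjusted p of 0.0150 for each. The only other probe of Lypd6 was at -1.30 and that of Itgb3 at -0.09. Those that fell most were Kif11, Usp15, Dgkh, Tcra, B3galnt1 and the proteoglycan gene Dcn, all with at least 1 array at the floor, with fitted means between -4.58 and -3.16 and adjusted p between 0.0063 and 0.0243. In all, 7131 probes were called, 3939 higher and 3192 lower, and 6820 of them had the same sign on all 4 arrays. The 4 probes called in both lines were those of Kif11, Usp15, Trpc1 and Zpr1, all lower. In HEK they had means of -2.52 for Kif11, -1.81 for Trpc1 and -1.51 for Zpr1, and Usp15 was at -2.04 and -1.95 on the HEK arrays. Of the probes called in HEK, 93.5% had the same sign in A23, against 73.9% of all probes. Among the 937 receptor probes 35.1% were called over both lines (95% exact interval 32.1 to 38.3), against 22.95% of the other named probes. The interval takes probes of the same 4 arrays as independent, so it may be too narrow. Centring each array left 1839 higher and 3873 lower, and the count was 144 without HEK replicate 1, 4482 without A23 replicate 1 and 3192 without A23 replicate 2.

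Across the 29563 probes, which are not independent replicates, the Pearson correlation was 0.55 between the A23 replicates and 0.589 between the HEK replicates, with Spearman values of 0.577 and 0.615. Between arrays of different lines the mean Pearson correlation was 0.491 and the mean Spearman correlation 0.505, from 0.431 to 0.559 over the 4 pairs. A pair of A23 replicates shared the sign at 72.4% of probes and the HEK replicates at 73.8%, against 66.7% to 71.9% between lines. The SD of the log2 ratios was 0.67 and 0.81 on the A23 arrays and 1.00 and 0.77 on the HEK arrays. For 1511 genes with 2 probes of different accession, the Spearman correlation across genes between the mean log2 ratios of both probes was 0.0618 (95% bootstrap interval 0.0107 to 0.112).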

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

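The tests of the Pcdh7 probes, of the slide position and of the correlation and spread of A23 replicate 1 were chosen after the result was seen, while those on receptor probes, same-gene probes and cell type markers were written before their values were computed.

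Of all probes, 2 had an effect that differed between the cell lines by the test of the difference itself. Gm39091 was higher in HEK than in A23 by at least 5.63 on the log2 scale (adjusted p = 0.0184), with both A23 arrays at the floor of the ratios and the HEK arrays at -0.61 and -1.43. Gm26698 differed by -5.46 or more in size (adjusted p = 0.0184), with both HEK arrays at the floor and the A23 arrays at -1.44 and -0.93. For each, the line at the floor shows no spread, so the p rests on the spread of the other line and limma's prior. Each has no other probe among those tested, and leaving out probes with a value at 0 or at the floor removes both, after which 0 probes differed in limma.

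The log ratios of the A23 and HEK arrays were correlated although the lines are of different species, with a mean Spearman correlation of 0.505 over the 4 array pairs. A transcriptional response common to both lines as the whole cause is argued against by olfactory, vomeronasal and taste receptor probes, whose genes fibroblasts and kidney cells are not known to express as a class: 35.1% of them were called over both lines, against 22.95% of the other named probes. Of the receptor calls 84.8% were higher, and centring each array cut all higher calls over both lines from 3939 to 1839. The receptor share was not computed with arrays centred, so how much of its excess would remain is not known. The 2 probes of the 1511 genes with such a pair correlated at 0.0618. That met the bound set beforehand against a response of genes rather than of single probes. It cannot decide the question, because 2 mouse probes of a gene may match hamster or human RNA unequally, and signal over background is unknown. A position trend is argued against by the between-line correlation of 0.552 that remained after the local medians were taken off. A bias at the level of single probes (dye, background or cross-hybridisation) is consistent with the receptor probes' correlation between lines, 0.552 (95% bootstrap interval 0.514 to 0.585), which lies above the 0.485 of the other named probes. That interval takes probes of the same 4 arrays as independent, so it may be too narrow. A dye effect cannot be told apart from an effect of Pcdh7 here, because 0 arrays had the dyes swapped, and a response of a smaller set of genes in both lines stays open.

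Pcdh7 was transfected on every array, yet its probes were not higher. Turned dyes or ratios cannot be told apart from the stated direction by these probes: the lowest value of the higher Pcdh7 probe over the 4 arrays was -0.35, which shows neither a strong rise nor a strong fall. Whether the probes read outside the transfected insert cannot be told apart from a low level of expression here, since 0 probe or insert sequences were used. No biological explanation was tested.

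The Cy3 source label of A23 replicate 1 names HEK. That this channel held HEK RNA cannot be told apart from a mistake in the label alone. Its Spearman correlation with A23 replicate 2 was 0.577, but A23 replicate 2 also correlated at 0.559 with HEK replicate 1. The SD of log ratios on A23 replicate 1, 0.67, was the lowest of the 4 arrays, while the SD of a comparison of hamster with human RNA on these probes was not measured. Cell type markers do not decide it either: the median of the fibroblast markers minus that of the HEK-type markers was 0.13 higher on replicate 1 than on replicate 2, which met the bound set beforehand against HEK RNA (below 0.5, where at least 1 was set for it). Both bounds assumed how far these mouse probes separate hamster from human RNA, which was not measured, so they were not well founded.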

How the results depend on the processing

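The alternatives were fixed before the data were examined, except the position correction and the phosphatase list without Taf1, which were chosen after seeing the data. The counts of probes and lists that moved by over 1.5 times, or across the threshold, follow, and the cause was not tested. In A23, 6 probes were called, and 1960 with arrays scaled to the same spread, 162 with robust moderation, 125 without values of 0 or at the floor, 2 among the probes with larger ratios, 37 over gene means, 29 position corrected, 572 at an adjusted p under 0.1, 2 with its own arrays alone and 1545 by size without a test; leaving out 1 array gave 2 to 818. In HEK, 3076 were called, and 1985 with arrays centred, 0 scaled, 2 among the probes with larger ratios, 5284 position corrected, 9247 at 0.1 and 5425 with its own arrays alone; leaving out 1 array gave 49 to 5425. Between the lines, 2 probes were called, and 0 scaled, 0 without values of 0 or at the floor and 0 among the probes with larger ratios; leaving out 1 array gave 9 to 220. Over both lines, 7131 were called, and 4204 scaled, 4133 over gene means, 11715 at 0.1 and 1449 with a mean of at least 1 in size; leaving out 1 array gave 144 to 8761. Of the lists, 1 passed in A23, and 2 scaled, 0 with an estimated correlation and 0 in fry, with 0 to 2 when 1 array was left out. In HEK 2 passed, and 1 centred, 0 scaled, 0 with an estimated correlation, 1 with probes as members, 0 position corrected and 1 in fry, the phosphatase list and neither of those 2, with 0 to 1 when 1 array was left out. With the replicate number as a replicate block the counts were 1245 in A23, 5108 in HEK and 49 between lines; replicate 1 minus replicate 2 correlated at -0.0965 between the lines, over only 2 pairs, so the arrays share only a number. Pcdh7 moved by less than the spread between arrays and the Pearson correlations, averaged over the pairs of a kind, by less than 0.1 in every setting. The Spearman correlation of A23 replicate 1 with HEK replicate 1 went from 0.431 to 0.549 position corrected. Pcdh7 ranged from -0.40 to -0.01 in A23 and from -0.12 to 0.22 in HEK. Without Taf1 no list crossed the threshold in camera. Centring turned the balance of calls, from 1665 higher and 1411 lower to 367 and 1618 in HEK and from 3939 and 3192 to 1839 and 3873 over both lines. All 24 named HEK genes kept their sign, but 0 still passed with arrays scaled, 18 centred, 19 position corrected, 7 without HEK replicate 1 and 5 without HEK replicate 2. Where an array was left out, the lone array of that line is taken to vary like the other line. Signal over background was not analysed here, and the number of arrays limits the precision.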

Other observations

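The gene families below, and the correlation of same-gene probes within each line and in their difference, were chosen after the result was seen; the same-gene test over all 4 arrays was written before its value was computed.

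Among 18 gene families defined by symbol, the olfactory, vomeronasal and taste receptors were the only one to pass in camera in either line without position correction. In A23 the median over 900 genes was 0.27, 668 had a positive mean and the adjusted p was 5.35e-05, or adjusted p = 0.959 with an estimated correlation. In HEK the median was 0.46, 699 genes were positive and the adjusted p was 1.57e-04, or adjusted p = 0.962 with an estimated correlation. These receptors are known from sensory neurons and taste cells. Of their 138 probes called in HEK, 114 were higher and 24 lower, and of those called over both lines 84.8% were higher, against 54.6% for the other named probes. The median stayed positive when arrays were centred, at 0.20 in A23 and 0.28 in HEK, and when they were scaled, at 0.42 and 0.29.

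Keratin-associated protein genes, of the hair shaft, had a median of 0.22 over 34 genes in A23 (adjusted p = 0.0948, or 0.0266 position corrected; adjusted p = 0.959 with an estimated correlation and no position correction) and of 0.35 in HEK (adjusted p = 0.16). Tubulin genes had a median of 0.40 over 20 genes in HEK (adjusted p = 0.109, or 0.0395 position corrected; adjusted p = 0.962 with an estimated correlation and no position correction), with 17 positive, and of 0.10 in A23 (adjusted p = 0.501). Proteasome subunits had 0.36 over 40 genes in HEK and translation initiation factors 0.42 over 50 genes, each with an adjusted p of 0.109. Their medians on HEK replicates 1 and 2 were 0.64 and 0.12 for the proteasome and 0.62 and 0.30 for the initiation factors. Homeobox genes of the Hox clusters had medians of -0.01 on either A23 array and of 0.53 and 0.26 on the HEK arrays, with a difference between lines at an adjusted p of 0.365. Immunoglobulin segments had a median of -0.18 over 14 genes in HEK (adjusted p = 0.225), with -0.42 on replicate 1 and 0.11 on replicate 2, and -0.02 after position correction.

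Probes of 1 gene moved almost independently of each other in each contrast. Over the 1511 genes with a pair of probes of different accession, the Spearman correlation between both probes was 0.0675 for the A23 mean, 0.033 for the HEK mean and 0.0073 for the difference between lines, and 0.0618 for the mean of all 4 arrays. The interval for pairs shuffled between genes, -0.0737 to 0.0277, lay mostly below no correlation, so it is not taken as the range without any relation. The same probe correlated at 0.625 between the A23 mean and the HEK mean.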
